A study of Mus musculus with 4 samples.

How the data were processed

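Bronchial epithelial cells from mouse lungs were profiled on 4 single-colour Agilent arrays, 1 per group: wild-type control, control labelled Pla2g3-/-, wild-type challenged and challenged labelled Pla2g3-/-. Per the labels' protocols, RNA was pooled from 4 samples for each, and each labelling reaction started from 200 ng of it with a low-input Cy3 kit. The injections were given in 0.2 ml, per the labels. Whether the 4 pooled samples were single mice, and what control mice received, is not given in the sources used here, so the challenge effects can include sensitisation. Groups were taken from the labels alone.

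The deposited scanner files hold intensity values per spot from Agilent Feature Extraction 11.5.1.1, per the file headers, which subtracted a background by spatial detrending and applied a multiplicative detrending. The probes were placed on the mm9 build, per the file headers. The series matrix deposited by the authors holds intensity values too. Set against the scanner values, each of its columns equalled the processed signal divided by that array's 75th percentile, to a near-exact match on the log2 scale (the ratio ranged over 1.59e-06 at most across an array) for 44397 of 44397 features. Its scale, centring and direction are thereby known, and its column medians were 0.0875, 0.0879, 0.0860 and 0.0850. The 4 arrays share 1 slide and 1 scan day and hold 4 positions on it, 1 group each, so position and group cannot be told apart.

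From the processed signal, the log2 value minus the array's 75th percentile was taken over 43020 spots that are not controls. Outlier spots were left out (135, 140, 128 and 155 per array), spots of 1 probe were averaged, and no spot was saturated. The local background had a median of 25 to 25.5 intensity units. Of 39429 probes, 28330 were matched to a RefSeq accession and took their symbol from a RefSeq gene table built on GRCm38.p6, used for names and gene order only, and 11099 kept the file's name. Of all probes, 3378 have no gene name, and 19 were left out for a missing value. The 27772 genes were each represented by the brightest probe, with 6704 genes having 2 or more probes and 21068 having 1. Where several probes were measured on both arrays and the chosen probe differed at least 2-fold, all probes had the same sign in 82.5% and 87.1% of genes for the challenge effects in wild type and in cells labelled Pla2g3-/-, and in 79.3% and 74.8% for the genotype effects without and with challenge.

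A gene not well above background on 1 of 2 arrays has only a bound there. The brighter value was set against the higher of the lowest signal well above background and the dim probe's own, so such a difference is given as "at least". Genes not well above background on either array have no value. Of the genes counted as 2-fold higher or lower, 160 and 142 were bounds for challenge in wild type, 242 and 193 for challenge in cells labelled Pla2g3-/-, 163 and 131 for genotype without challenge, and 226 and 199 for genotype under challenge. The number of arrays limits the precision. The scanner's own error of a difference had a median of 0.22 over named genes for genotype under challenge, and ranged from 0.06 to 2.03 over the effects of named genes. Of the 399 probes printed 10 times, those well above background (333 to 345 per array) had a median SD of 0.07 between spots on each array.

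The first 4 effects were single differences between 2 arrays, the fifth the difference between the 2 challenge effects, and genes at least 2-fold different were counted. Overlaps were set beside the number that independent lists would share. An additive limma fit of genotype and challenge, with 1 residual degree of freedom, a trend on the mean level and Benjamini-Hochberg adjustment at 0.05, was the only test across arrays. It assumes that the 2 effects add up, so a true difference between genotypes counts as its error. Gene lists were 52 lists written before the data were examined, covering cell types, epithelial and inflammatory programmes, lipid-mediator genes and the region around Pla2g3, and 3 lists added afterwards. Each list's median was set among 10000 random lists of the same size, matched on mean level in 20 bins, as a description of these arrays.

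Genes were named by a rule fixed before the data were examined. Pla2g3 came first on every array. Then, per effect, came the 12 genes with the largest positive and the 12 with the largest negative difference of at least 1 on the log2 scale, among genes with a symbol that is not a clone or prediction name, well above background on the arrays compared, not saturated, at or above the 25th percentile of detected probes on the brighter array, and with all measured probes of 1 sign. The filter on names missed 1 clone name, A530028O18, which is named in the report as such. Up to 5 bounds per direction and up to 4 members of each list with the largest difference could be named beside them. Alternatives were normexp background correction with an offset of 50, quantile normalization, only genes above background on all 4 arrays, no filter on dim probes, the mean of a gene's probes, the series matrix values, the fit without a trend, and genes 2-fold different in either genotype. Exchanges of the control arrays were added after seeing the data.

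The steps were tested on simulated data. In the 2-fold count for challenge in wild type, simulated over 22358 genes, 100 of 100 genes planted at log2 2 and 0 of 100 planted at 0.5 were counted, with 0 of 22158 unchanged genes. The noise there was that of repeated spots only (SD 0.10 of a difference), alike for all probes, with detection the same on all arrays. At that noise the 0 false counts were fixed in advance. They say nothing of error between pools, labellings or hybridisations, of dim probes or of bounds. Of 200 random lists of 15 genes, 9 unshifted ones fell outside the central range, and 200 of 200 shifted by 0.5 did. Random genes were set among random genes there, so these outcomes were largely fixed in advance. They say nothing of lists of genes that vary together. The additive fit was simulated for challenge over 22553 genes with 2 kinds of noise. With variances drawn from the fitted prior it called 0 of 100 genes planted at log2 1, 47 of 100 planted at log2 2, and 3 of 22353 unchanged genes. With each gene's moderated residual variance it called 79, 99 and 60. The second kind was the only one at first. The first kind was put in its place after its false calls had been seen, and why it gave so many was not tested, so both are given. The rule of 2-fold in both genotypes took 21 and 100 planted genes and 48 unchanged ones with the first kind, and 25, 99 and 25 with the second. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.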

Results

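Gene expression was measured in bronchial epithelial cells taken from mouse lungs in a model of allergic asthma, with ovalbumin (OVA) as the allergen. The mice were wild type (Pla2g3+/+) or labelled as lacking Pla2g3 (Pla2g3-/-), the gene of group III phospholipase A2, a secreted enzyme that releases fatty acids and lysophospholipids from membrane phospholipids. Each genotype had a challenged group and a control group. Per the labels, sensitisation was by injection of 10 µg OVA with 1.3 mg alum on days 0 and 14, the aerosol held 1% OVA and was given for 30 min on days 26, 27 and 28, and lungs were taken 3 h after challenge. What the control mice received is not stated, so a challenge effect below can include an effect of sensitisation. RNA pooled from 4 samples was hybridised to 1 single-colour array per group, 4 arrays in all, on 1 slide. No difference below therefore has a replicate check, and no p-value is given for a single comparison.

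Between 78.7% and 81.5% of probes were well above background on each array, and 21593 of 27772 genes were so on all 4 arrays. The 75th percentile of signal was 1986 and 1834 intensity units on the wild-type control array and that labelled Pla2g3-/-, and 1808 and 1979 on the wild-type challenged array and that labelled Pla2g3-/-. Values are log2 differences between arrays after each was scaled to that percentile, so 1 is a 2-fold difference. Repeated spots of 1 probe well above background gave a median SD of 0.10 for such a difference, and 0.13 to 0.15 among the dimmer of these probes. Some probes were far noisier. The 95th percentile of the SD between spots of 1 probe was 0.33 to 0.50 per array, and 0.48 to 0.70 among the dimmer probes. The median SD between different probes of a gene was 0.09 to 0.10. These errors cover spots and probes only, not animals, pools, labelling or hybridisation. A list of genes is described by its median, which lay outside the central 95% of 10000 random lists matched on level unless a percentile is given or the median belongs to an alternative setting.

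Pla2g3 was reported first because it checks the labels, and it went against them. Its signal was higher, not lower, in the arrays labelled Pla2g3-/-. The chosen probe, on chromosome 11 from 3394109 to 3394168 (mm9), read 239 and 254 intensity units on the wild-type control and challenged arrays, and 2023 and 4154 on the 2 arrays labelled Pla2g3-/-. That is a log2 difference of 3.19 without challenge (9.14-fold) and 3.90 with challenge (14.9-fold), each with a scanner error of 0.20. A second probe, from 3393127 to 3393186, gave 2.12 (4.35-fold) and 4.56 (23.5-fold). The 4.56 rests on a dim value, since this probe read 13.1 units on the wild-type challenged array. That is −7.11 on the log2 scale, near the lowest detected value there (−7.82). For challenge in wild type the first probe gave 0.22 and the second −1.62. The labels do not say which part of the gene is missing, so whether either probe lies inside the deleted part is unknown, and a probe outside it checks nothing. Every genotype direction below rests on the labels as given, and the arrays are called "labelled Pla2g3-/-" for that reason.

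**Figure D1:**
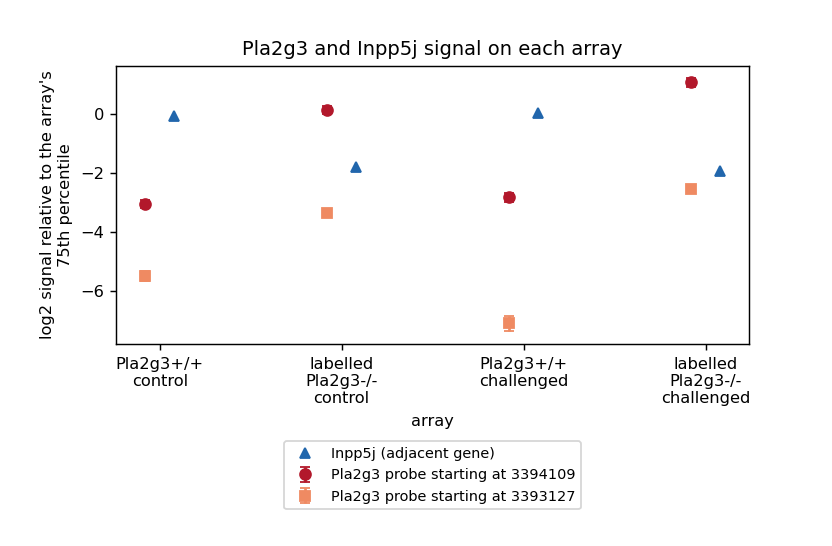
Log2 signal relative to each array's 75th percentile (vertical axis) on the 4 arrays (horizontal axis) for the 2 Pla2g3 probes and the adjacent gene Inpp5j, with the scanner's error as bars on the Pla2g3 probes. Both Pla2g3 probes sit higher on the arrays labelled Pla2g3-/- than on the wild-type arrays, and Inpp5j sits lower.

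Genes next to Pla2g3 were mostly alike in the 2 genotypes. Of 30 measured genes of the surrounding region, 1 was at least 2-fold lower between the control arrays, and 1 was higher and 1 lower between the challenged arrays. The lower gene was Inpp5j, an inositol polyphosphate phosphatase gene adjacent to Pla2g3, with −1.73 and −1.98. The higher gene was Osm, which encodes oncostatin M, with 2.52 between the challenged arrays. The adjacent gene on the other side, Rnf185, differed by −0.21 and 0.00.

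The first comparison asked which genes differed between challenged and control cells in both genotypes. Cxcl5, a chemokine that attracts neutrophils, was higher by 6.93 in wild-type cells (122-fold) and by 6.56 in cells labelled Pla2g3-/- (94.6-fold). The anion exchanger gene Slc26a4 (pendrin) was higher by 4.62 and 4.19, Lcn2, an iron-scavenging antimicrobial protein, by 3.89 and 3.36, and Pla2g4c, a cytosolic phospholipase A2, by 4.03 and 2.95. Further genes higher in both were Slfn4 (3.47 and 4.34), the lipase gene Lipf (3.22 and 3.47), the potassium channel gene Kcnj15 (3.19 and 4.09), the noncoding RNA Mirt2 (3.08 and 4.59), the chitinase-like gene Chil5 (2.70 and 3.47), Ccl17, a ligand of CCR4 (2.69 and 4.45), Cstdc4 (2.69 and 4.74) and the acute phase gene Saa3 (2.56 and 4.63). Genes lower in both included Dbp, an output gene of the circadian clock (−1.42 and −1.80), carbonic anhydrase 3 (Car3, −1.56 and −1.81), Grap (−1.54 and −1.70), Pde5a (−1.83 and −1.37) and Dact2 (−1.33 and −1.47).

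Several of the other genes lower in both are genes of lymphocytes: Gpr174 (−2.10 and −2.01), Gimap6 (−1.39 and −1.68), Prkcq (−1.37 and −2.06), P2ry10 (−1.25 and −1.81), Lef1 (−1.35 and −3.59) and Cd3d (−1.26 and −3.24). The control array labelled Pla2g3-/- stood apart in such genes, as given below, with a T cell list 2.39 above the wild-type control array. Pth, parathyroid hormone, was −5.12 in wild type and −1.46 in cells labelled Pla2g3-/-, and was highest on the wild-type control array.

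In wild-type cells 419 genes were at least 2-fold higher and 397 lower after challenge, and in cells labelled Pla2g3-/- 895 were higher and 796 lower. Of 22704 genes measured in both, 176 were higher in both against 12.3 from independent lists, and 83 were lower in both against 11.48, while 50 and 44 went opposite ways. By the sizes of the lists, independent ones would share fewer than 12.3 in each opposite way, so the opposite counts lie above that as well. Across 21593 genes, which are not independent replicates, the 2 effects had a Pearson r of 0.41 and a Spearman rho of 0.38. With normexp background correction the wild-type counts were 126 and 57, those in cells labelled Pla2g3-/- were 374 and 318, and those in both were 95 and 13. With the other control array put in place of the wild-type one, an alternative chosen after seeing the data, the wild-type counts were 526 and 959.

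**Figure D2:**
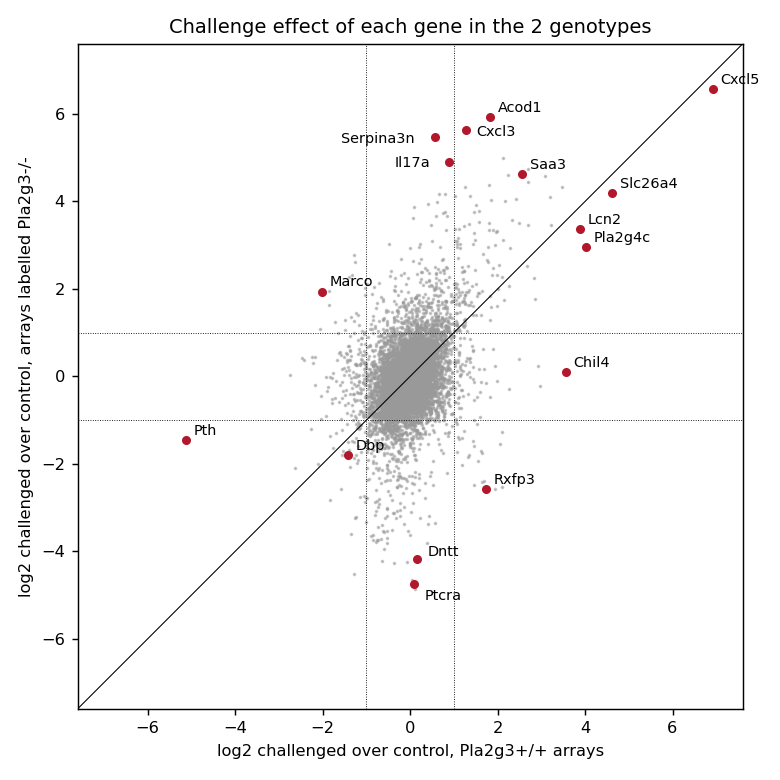
Log2 difference between challenged and control arrays in wild-type cells (horizontal axis) and in cells labelled Pla2g3-/- (vertical axis), 1 point per gene above background on all 4 arrays, with a line of equality and dotted lines at 2-fold. Cxcl5 lies near the line at 6.93 and 6.56, Serpina3n far above it at 0.56 and 5.47, and Ptcra far below it at 0.09 and −4.75.

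Lists of secretory and stress genes used by the airway epithelium were higher after challenge in both genotypes. Which cells of the pools gave the rise was not tested. The list of goblet cell and mucus genes had medians of 0.42 and 0.63, with 3 of 15 genes at least 2-fold higher in each. Muc5ac, the main induced airway mucin, had effects of 0.86 in wild type and 1.15 in cells labelled Pla2g3-/-, Spdef, a regulator of goblet cell fate, 0.42 and 1.05, and Clca1, a secreted goblet cell protein, 1.89 and 0.63. Genes of the epithelial response to type 2 cytokines had medians of 0.42 (6 of 21 higher, 1 lower) and 0.93 (10 of 21 higher), including Retnla (2.68 and 2.52) and Retnlb (at least 2.92 and 3.33, since it was not well above background on the control arrays). This list shares members with the goblet cell and mucus list, among them Clca1, Muc5ac, Spdef and Slc26a4. The medians of these lists are therefore not independent. Acute phase and antimicrobial genes had medians of 0.51 (5 of 18 higher) and 0.80 (6 of 19), including Saa1 (1.78 and 2.96) and Orm1 (1.99 and 1.60).

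Genes of the unfolded protein response, which answers a load of misfolded protein in the endoplasmic reticulum, had medians of 0.73 and 0.65, with Chac1 at 1.13 and 1.86. Interferon response genes had medians of 0.53 (1 of 23 higher) and 0.77 (5 of 23), led by Cxcl10 at 1.80 and 4.38. Genes of the NRF2 antioxidant programme had medians of 0.41 and 0.31, with the cystine transporter gene Slc7a11 at 1.84 and 1.29. Circadian clock genes were lower, with medians of −0.48 and −0.43 and 2 of 16 at least 2-fold lower in each. In wild-type cells these 2 were Ciart (−1.63) and Dbp, and in cells labelled Pla2g3-/- they were Dbp and Hlf (−1.03). The labels give no time of collection for the control mice. For clock genes the hour of collection therefore cannot be told apart from challenge. Xenobiotic cytochrome P450 and related genes were also lower, with medians of −0.26 and −0.40, the second −0.26 under quantile normalization.

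Chemokine, cytokine and neutrophil genes were higher after challenge in both genotypes, by more on the arrays labelled Pla2g3-/-. In wild-type cells 11 of 24 chemokine genes were at least 2-fold higher and 2 lower (median 0.30), and in cells labelled Pla2g3-/- 19 of 25 were higher (median 2.31). Cxcl3 was 1.27 and 5.62 higher, and Ccl7 2.13 and 4.98. Epithelial cytokine genes had medians of 0.44 (3 of 15 higher) and 1.94 (11 of 17), with Il1b at 2.23 and 4.62 and Il6 at 0.53 and at least 4.73. Neutrophil genes had medians of 1.15 and 1.88, with 8 of 15 higher in each and 1 lower in the second (Mpo at −1.12, named after its value was seen), including the receptor gene Cxcr2 (1.99 and 3.32) and the calprotectin subunit S100a9 (1.76 and 2.65). In cells labelled Pla2g3-/- macrophage genes (0.46, 3 of 16 higher), dendritic cell genes (0.94, 3 of 10) and endothelial genes (0.56, 4 of 14) were higher with them, while in wild type these lists had medians of −0.04, −0.03 and −0.04 (34.2nd, 54.2nd and 52.3rd percentiles). Pan leukocyte genes went the other way, with medians of −0.59 in wild type (none of 12 at 2-fold) and −0.24 in cells labelled Pla2g3-/- (3 higher and 1 lower). Under normexp the dendritic and endothelial medians in cells labelled Pla2g3-/- were 0.61 and 0.11. With the mean of a gene's probes the dendritic medians were −0.29 in wild type and 0.52 in cells labelled Pla2g3-/-. NF-kB feedback genes had medians of 0.24 and 0.83, with Bcl3 at 1.06 and 2.05. Whether these genotype differences exceed the spread between pools was not tested, since each group had 1 array. With only genes above background on all 4 arrays the epithelial cytokine medians were 0.17 and 0.63, and with normexp background correction they were 0.22 and 0.85 and the neutrophil medians 0.64 and 1.09.

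Lymphocyte genes had unlike challenge effects in the 2 genotypes, and the control arrays themselves differed in these genes. T cell genes had medians of −0.34 (2 of 16 higher, 2 lower) and −1.61 (2 higher, 9 lower). The genes higher were the cytokines Il5 (at least 2.76 and 5.18) and Il13 (at least 2.19 and 4.67), and those lower in cells labelled Pla2g3-/- included Cd8a (−3.73, against −0.84 in wild type) and the T cell kinase gene Lck (−3.24, against −0.58). B and plasma cell genes were lower in wild-type cells, with a median of −1.15 and 7 of 11 at least 2-fold lower, including Ms4a1 (−1.56) and Cd79a (−1.40). Under normexp that median was −0.72, and with only genes above background on all 4 arrays the wild-type T cell median was −0.55. In cells labelled Pla2g3-/- their median was 0.11 (93.4th percentile), with none of 11 at 2-fold. The median level of the B cell list was −1.29 on the wild-type control array and −2.85, −2.58 and −2.61 on the others. That of the T cell list was −0.74 on the control array labelled Pla2g3-/- and −3.35, −3.94 and −2.69 on the others.

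**Figure D3:**
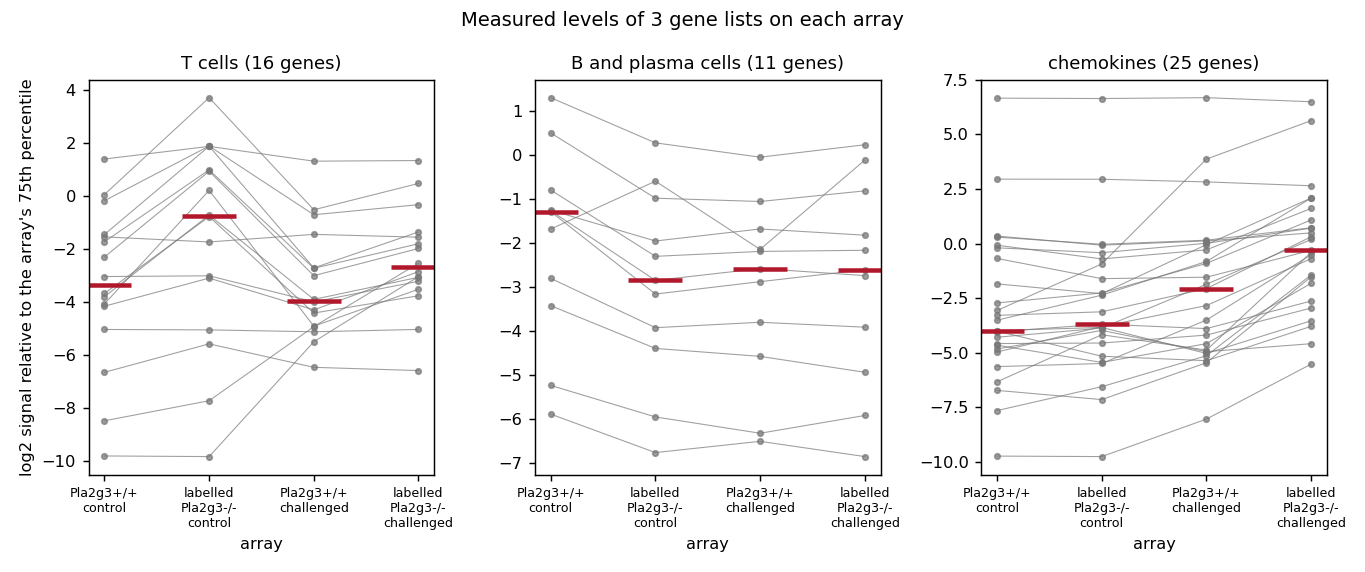
Log2 signal relative to each array's 75th percentile (vertical axis) of the genes of 3 lists on the 4 arrays (horizontal axis), with 1 grey line per gene above background on at least 1 array and the list's median in red. The T cell median is highest on the control array labelled Pla2g3-/- at −0.74, the B cell median on the wild-type control array at −1.29, and the chemokine median on the challenged array labelled Pla2g3-/- at −0.31.

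An additive fit with limma, which takes the disagreement between the 2 genotypes as its error, called 4 genes for the average challenge effect, all higher. They were Cxcl5 (6.75, adjusted p = 0.00802), Lipf (3.34), Slc26a4 (4.41) and the resistin-like gene Retnla (2.60), the last 3 each with an adjusted p of 0.0394 (limma). Each was higher in both genotypes. Lcn2 (3.62) missed the threshold with an adjusted p of 0.0512, and 3491 of 22553 genes had an unadjusted p under 0.05. On simulated data the fit called 3 of 22353 unchanged genes with variances drawn from its prior and 60 with each gene's own moderated variance. It has 1 residual degree of freedom, and without a trend in its variance it called 0 genes, with 2802 at an unadjusted p under 0.05.

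The second comparison set the control array labelled Pla2g3-/- against the wild-type control array, which asks what the genotype does without challenge. The genes most above wild type were led by genes of developing T cells. Rag1 and Rag2, which cut and join antigen receptor genes, were higher by 5.80 and 5.44, Dntt, which adds bases at the joins, by 5.60, and Ptcra, the pre-T cell receptor alpha chain, by 4.92. Endou (5.66), H2-T3 (4.94), Sh2d1a (4.94), Trat1 (4.42), Myl10 (4.99), Chrna9 (4.92), Tmem151b (4.42) and Syt13 (4.32) complete the 12 named in this direction. T cell genes had a median of 2.39, with 10 of 14 at least 2-fold higher, including Cd8a (4.29), Lck (3.66), Cd3d (3.33) and Cd3g (3.24). In a list of thymocyte genes written after these values were seen, 19 of 20 were higher, with a median of 4.09. Cell cycle genes had a median of 1.03 (11 of 21 higher), with Top2a at 1.59, pan leukocyte genes one of 0.65 (5 of 12 higher) and neutrophil genes one of 0.71 (2 of 15 higher, 0.38 under normexp).

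Genes lower on the control array labelled Pla2g3-/- were led by Slc26a4 (−3.54), followed by Tmem221 (−3.04), Trim69 (−2.74), the protease inhibitor gene Serpina3n (−2.67) and the growth factor gene Areg, amphiregulin (−2.35). Tnfrsf13c (−2.33), which encodes the BAFF receptor, Fcrl1 (−2.13) and Fcmr (−2.05) are genes of B cells, and the B cell list had a median of −1.03 with 6 of 11 lower and 1 higher. Dcstamp (−2.26), the endothelial gene Mmrn2 (−2.14), Pth (−2.11) and the phosphatase gene Dusp8 (−2.05) were also lower. Endothelial genes had a median of −0.46 with 5 of 14 lower, including Cldn5 (−1.44), and interferon response genes one of −0.35 with 1 of 23 lower. Trim12a was not well above background on either array labelled Pla2g3-/-, with a difference from wild type of −7.29 or lower without challenge and −6.68 or lower with it. In all, 755 genes were at least 2-fold higher and 418 lower of 23240 measured. With normexp background correction the counts were 356 and 95, and the endothelial median was −0.24. No other array could stand in for either control here.

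The third comparison set the challenged array labelled Pla2g3-/- against the challenged wild-type array, the effect the study's title names. Neutrophil-attracting chemokines and inflammatory cytokines were higher on the array labelled Pla2g3-/-: Cxcl1 by 4.47, Cxcl3 by 3.94, Cxcl2 by 3.70, Il17a by 4.03, Il1b by 3.38 and Il1f9 by 3.33. Also among the 12 were Acod1 (3.36), which makes itaconate, the lectin receptor genes Olr1 (3.65) and Clec4e (3.18), and Mefv (3.12), which encodes pyrin. The sensory receptor gene Mrgpra6 (3.49) and Pla2g3 itself complete the 12. Of 25 chemokine genes, 19 were at least 2-fold higher (median 1.90). Of 17 epithelial cytokine genes, 9 were (median 1.00), including Il6 (3.01) and Csf3 (2.75), and of 15 neutrophil genes, 10 were (median 1.66), including G0s2 (2.54) and Cxcr2 (2.39). The neutrophil list was already 0.71 higher between the control arrays.

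Several other leukocyte lists were also higher on that array, but not all. Macrophage genes had a median of 0.71 (4 of 16 higher), with the scavenger receptor genes Marco and Msr1 at 2.58 and 2.51. Dendritic cell genes had one of 0.84 (3 of 10 higher), with Ccl17 at 2.90, and pan leukocyte genes one of 1.07 (7 of 12 higher). T cell genes had a median of 0.88 (6 of 16 higher), led by the type 2 cytokines Il13 (2.46) and Il5 (2.40), while the thymocyte list had one of 1.02 (10 of 20 higher). Natural killer cell genes had a median of 0.20 (0.007 under normexp) with none of 9 at 2-fold, B and plasma cell genes one of 0.03 (82.0th percentile, 1 of 11 higher), and mast cell and basophil genes one of −0.12 (19.9th, 1 of 11 higher). Immediate early genes, which answer a stimulus within minutes, had a median of 0.61 (4 of 21 higher), including Egr2 (2.60) and Fosl1 (1.71). NF-kB feedback genes had a median of 0.73 (3 of 14 higher), including Tnfaip3 (1.49). With normexp background correction the dendritic cell median was 0.49 and that of the thymocyte list 0.58, and with only genes above background on all 4 arrays the epithelial cytokine median was 0.63.

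Genes lower on the challenged array labelled Pla2g3-/- were led by Slc26a4 (−3.97). The others were Rxfp3 (−3.30), Oxct2b (−3.16), Neurod2 (−2.79), Defb26 (−2.67), Dnajb8 (−2.65), Gal3st2 (−2.59), Angptl7 (−2.58), Dsg1c (−2.53), Kif12 (−2.38), Wfdc6a (−2.15) and Trim43b (−2.00). That array had the lowest share of probes well above background, 78.7% against 81.5% on the challenged wild-type array. Whether this difference in detection bears on these genes was not tested. Goblet cell and mucus genes had a median of 0.02 (93.0th percentile), with Slc26a4 the 1 of 15 at 2-fold, and interferon response genes had one of −0.18, with Cxcl10 the 1 of 23 at least 2-fold higher (2.13). In all, 897 genes were at least 2-fold higher and 569 lower of 23339 measured. With normexp background correction the counts were 287 and 142, and with only genes above background on all 4 arrays they were 601 and 360.

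**Figure D4:**
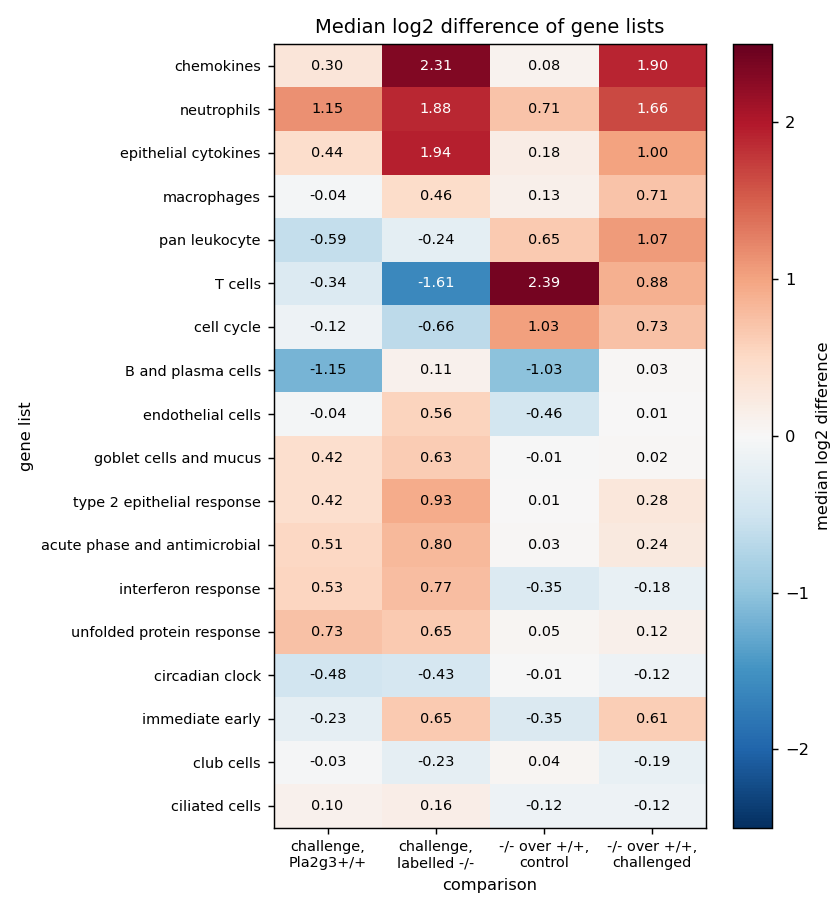
Median log2 difference of 18 gene lists (vertical axis) in the 2 challenge effects and the 2 genotype effects (horizontal axis), in colour and as a number. Chemokines stand at 2.31 for challenge in cells labelled Pla2g3-/- and at 1.90 between the challenged arrays, against 0.30 for challenge in wild type and 0.08 (96.4th percentile of random lists) between the control arrays.

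Genes that differed by genotype in both conditions come from separate pairs of arrays. Above wild type in both were Pla2g3, Pla2g4c (3.55 without and 2.47 with challenge), the noncoding RNA Zmiz1os1 (2.60 and 2.83), Rag1 (5.80 and 2.45), Zfp963 (2.35 and 2.43), the G protein subunit gene Gnb4 (2.44 and 2.19), Cxcl1 (2.16 and 4.47), the prostaglandin E receptor gene Ptger1 (2.39 and 2.09), Orm2 (2.32 and 2.05), the cathepsin gene Ctse (1.89 and 2.83), Usp13 (2.38 and 1.78) and Cxcl5 (2.13 and 1.76). Below wild type in both were Slc26a4 (−3.54 and −3.97), Gal3st2 (−2.00 and −2.59), the carboxylesterase gene Ces1b (−2.00 and −1.83), Dao, D-amino acid oxidase (−1.78 and −1.85), Sparcl1 (−1.99 and −1.78), Inpp5j, Tmem221 (−3.04 and −1.63), Dcstamp (−2.26 and −1.61), B3gnt3 (−1.61 and −1.72), Serpina9 (−1.57 and −1.88), Pttg1 (−1.48 and −1.88) and Il3ra (−1.43 and −1.45).

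Of 22753 genes measured in both, 193 were higher in both against 22.3 from independent lists, and 102 were lower in both against 8.58, while 36 and 41 went opposite ways. Independent lists of these sizes would share fewer than 22.3 in each opposite way, so these counts lie above that too. Across genes the 2 genotype effects had a Pearson r of 0.34 and a Spearman rho of 0.28. The additive limma fit called Trim12a (−6.98) and the predicted gene Gm5067 (−4.21), each with an adjusted p of 0.0427 and lower in both conditions, the second named outside the rule because it was called. Trim12a was not well above background on either array labelled Pla2g3-/-, so its −6.98 is the mean of 2 bounds and its p rests on floor values. In the same fit 2769 of 22602 genes had an unadjusted p under 0.05. With normexp background correction 60 genes were higher and 39 lower in both, and the fit called 9 genes. It called 0 with the mean of a gene's probes and 0 without the variance trend.

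The fourth comparison set the 2 challenge effects against each other, which has no residual error with 4 arrays and so was not tested. Genes with the larger challenge effect in cells labelled Pla2g3-/- were Serpina3n (0.56 in wild type and 5.47), Cxcl3, Acod1 (1.83 and 5.92), the T helper cytokine gene Il17a (0.88 and 4.90), Clec4e (0.08 and 3.88), Cxcl9, a ligand of CXCR3 (0.07 and 3.62), Serpina3g (0.67 and 4.17) and Mefv (0.63 and 3.98). Marco (−2.01 and 1.94), Cd5l (−1.85 and 1.94) and Dusp8 (−1.85 and 1.64) went opposite ways. Pth differed by 3.67. Chemokine genes had a median difference of 1.53 (14 of 23 at 1 or more), immediate early genes one of 0.90 (10 of 21) and B cell genes one of 1.12 (7 of 11), the last with the high wild-type control level given above.

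Genes with the lower value in cells labelled Pla2g3-/- included Ptcra (−4.83), Endou (−4.71), Dntt (−4.33), Rag2 (−3.80) and Sh2d1a (−3.56), which are in the thymocyte list written after the values were seen, where 18 of 20 were lower by 1 or more (median −2.90). These were high on the control array labelled Pla2g3-/-, as were Tmem151b (−3.88) and Syt13 (−3.62). Col2a1 (−3.92) and A530028O18 (−3.61), a clone name the naming rule failed to drop, were likewise higher on that control array, by 3.41 and 3.50. Chil4, a chitinase-like gene induced in allergic airways, was 3.56 higher after challenge in wild type and 0.09 in cells labelled Pla2g3-/- (−3.47), and was already 3.98 higher on the control array labelled Pla2g3-/-. Oxct2b (−4.06) and Defb26 (−3.48) complete the 12.

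Set against its own control array, the challenge effect was larger in cells labelled Pla2g3-/- among these pools, which was not tested. Over 544 genes chosen on the mean of both effects, the SD of the effect was 1.97 times that in wild type, and 466 genes had the larger effect. Over all genes measured, without such a choice, the SD was 0.62 in cells labelled Pla2g3-/- and 0.42 in wild type. The genes higher on average (296) had medians of 1.02 and 2.0, and those lower (248) had medians of −0.73 and −1.97, a set that includes the T cell genes high on the control array. In all, 613 genes differed by 1 or more upward and 585 downward of 21593, and with normexp background correction 259 and 293 did. Whether it is larger, and by how much, depends on the control array. With the wild-type control array for both, a choice made after seeing the data, 419 genes were higher and 397 lower in wild type against 951 and 753 in cells labelled Pla2g3-/-. With the other control array for both, the counts were 526 and 959 against 895 and 796, so more genes were lower in wild type.

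Genes of phospholipid and eicosanoid metabolism bear on the enzyme the labels name. Among 11 secreted phospholipase A2 genes, Pla2g3 was the only one at least 2-fold different between genotypes in either condition. The list's medians were −0.08 and 0.06 (45.9th and 87.0th percentiles), and with the mean of a gene's probes the first was 0.35. Under normexp they were 0.036 and −0.063. After challenge Pla2g2d was lower in both genotypes (−1.20 and −1.14), and Pla2g5 had effects of −0.36 and 1.02. Of 18 intracellular phospholipase A2 genes, Pla2g4c was the only one at 2-fold between genotypes, and was also the only one in wild-type cells after challenge, while in cells labelled Pla2g3-/- Pla2g7 was too (−0.11 and 1.03).

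Among 21 eicosanoid enzyme genes, Ptgs2 (cyclooxygenase-2) stood at −1.15 relative to wild type on the control array labelled Pla2g3-/- and at 1.62 on the challenged one, with challenge effects of 0.20 in wild type and 2.96 in cells labelled Pla2g3-/-. The lipoxygenase gene Alox12e was higher after challenge in both (2.04 and 2.55). Eicosanoid receptor genes had medians of 0.30 and 0.73 between genotypes, with 2 of 13 higher and 1 lower without challenge and 5 higher and 1 lower with it. Ptger1 was among those higher in both, with Fpr2 (2.64) and the prostacyclin receptor gene Ptgir (1.74) higher under challenge, and Ptgdr was lower in both (−1.17 and −1.53). With normexp background correction the challenged median was 0.14. Of 25 lysophospholipid genes, Lpcat2 (1.75 and 1.73) and Gpr132 (1.41 and 1.26) were higher in both conditions, S1pr1 was lower without challenge (−1.20), and the platelet-activating factor receptor gene Ptafr (1.78) and Enpp2, autotaxin (1.46), were higher under challenge. The list's medians were −0.01 (55.4th percentile) and 0.07.

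Club and ciliated cell markers differed little. None of 12 club cell and 20 ciliated cell genes was 2-fold different in any of the 4 effects. Club cell medians were −0.03 and −0.23 after challenge (20.4th and 9.14th percentiles) and 0.04 (15.8th) and −0.19 between genotypes without and with challenge, the last −0.05 under quantile normalization. Ciliated cell medians were 0.10 (95.8th percentile) and 0.16 after challenge and −0.12 and −0.12 between genotypes. Basal cell genes had medians of −0.17 and −0.02 (73.5th percentile) between genotypes, the second −0.145 with the mean of a gene's probes. After challenge they had medians of 0.02 and 0.02, inside the random range, with Icam1 (0.48 and 1.67) and Krt14 (0.92 and 1.43) at least 2-fold higher in cells labelled Pla2g3-/-. Fibroblast genes had medians of −0.24 and −0.18 after challenge, the second at the 14.1th percentile, and 0.12 (95.8th) and 0.33 between genotypes (the last 0.18 under normexp), with none of 14 at 2-fold. Eosinophil genes had medians of −0.21 and 0.09 after challenge (9.88th and 86.2nd percentiles), −0.06 (49.9th) between the control arrays and 0.44 between the challenged ones (1 of 8 higher, 0.23 under normexp). Of their challenge medians, that in wild type was −0.11 under normexp. That in cells labelled Pla2g3-/- was 0.29 with only genes above background on all 4 arrays.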

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

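The tests on Pla2g3, on the chemokine genes, and on mature T cells and genotype among the T cell genes were chosen only after the results were seen. The test on thymic epithelium used an added gene list and addressed a pattern already seen in the T cell genes. Only its bounds were written before its own result.

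Among the genes named by the rule for naming genes and above background on all 4 arrays, 13 had challenge effects of at least 2-fold and opposite direction in the 2 genotypes, which was not tested because each group has 1 array. Over all genes measured in both, 50 and 44 went opposite ways. Marco (a difference of 3.95 between the effects), a scavenger receptor gene of macrophages, Cd5l (3.79), a macrophage-secreted protein gene, and Dusp8 (3.49) were lower after challenge in wild type and higher in cells labelled Pla2g3-/-. The other 10 were higher in wild type and lower in cells labelled Pla2g3-/-: Rxfp3 (−4.32), Oxct2b (−4.06), Defb26 (−3.48), Neurod2 (−3.39), Dnajb8 (−3.23), Dsg1c (−3.18), Kif12 (−3.16), Angptl7 (−2.80), Wfdc6a (−2.63) and Trim43b (−2.60). For Rxfp3 and Dusp8 this rests on 1 of 2 probes, since the other gave 0.25 in wild type and 0.19 in cells labelled Pla2g3-/- for Rxfp3, and −0.87 and 0.40 for Dusp8. The 10 genes lower in cells labelled Pla2g3-/- were also lower on that challenged array than on the wild-type one. That array had the fewest probes well above background. Among probes with no gene name, which enter no comparison above, 11 were at least 2-fold higher after challenge in both genotypes, where independent lists would share 0.507. They come from 2171 such probes above background on all 4 arrays, of which 25 were higher in wild type and 44 in cells labelled Pla2g3-/-.

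Pla2g3 signal was higher on both arrays labelled Pla2g3-/-. An exchange of labels in 1 condition only is argued against, since both differences have the same direction and the smaller is 3.19, many times its scanner error. An exchange in both conditions stays open: the difference of 3.90 between the challenged arrays is what it would give, and no second marker of the genotype is at hand. A transcript of the altered allele, read by probes outside the deleted part, stays open as well, and the adjacent gene Inpp5j was lower by genotype in both conditions (−1.73 between the control arrays), which may reflect an altered locus. Under an exchange in both conditions every genotype direction above would turn around.

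Genes of developing T cells were highest on the control array labelled Pla2g3-/-. More mature T cells in that pool are argued against as the whole cause, since they would raise their genes of egress and memory alike, yet the T cell median exceeded that of these genes by 2.63 (bootstrap 95% interval 0.92 to 3.48). None of those 11 was 2-fold higher (−1.20 to 0.40), though other cells, such as B cells, whose markers were lower there, use several of them. Whole thymus tissue carried over could bring such genes. Its epithelial genes had a median of 0.85, with 2 of 7 at least 2-fold higher and a range from −0.54 to 2.01. That median lies between the bounds written before this result and leaves whole thymus tissue open. The genotype itself stays open as untested, with the thymocyte list at 1.02 between the challenged arrays and 1 pool per group.

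Chemokine and cytokine genes were higher on the challenged array labelled Pla2g3-/-. A smaller share of epithelial cells in that pool, with all other cell types raised alike, is argued against. The neutrophil median exceeded the endothelial one by 1.65 (bootstrap 95% interval 0.42 to 2.06, 10000 draws). A smaller share brought by more leukocytes stays open, since it would raise neutrophil genes above endothelial ones too. The pan leukocyte list had a median of 1.07 there. Scaling is argued against too, since the lower chemokine median over normexp and quantile scaling was 1.73. More neutrophils at unchanged expression per cell stays open for the lists as a whole. The chemokine and cytokine median lay only 0.17 above the neutrophil one (−0.67 to 1.51). The largest chemokine difference (4.47) lay above the largest neutrophil one (2.54). These are maxima of lists of unlike size, picked after the values were seen. They cannot decide whether more neutrophils account for each gene. The genotype stays open as untested, and the intervals cover the choice of genes, not animals.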

How the results depend on the processing

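The exchanges of control arrays and the 3 lists marked as added are tests chosen only after the results were seen, and all other alternatives were set before. The cause was not tested for any value below except where stated. No paired analysis was possible because each group has 1 array and no result of a single difference comes from a test, and no replicate could be left out. Of 1350 list medians under the alternatives, 1249 moved by less than the error of a difference, 100 moved by more and 1 changed sign among those called. Of 954 values of named genes, 739 moved by less, 215 by more (179 of them under normexp, whose offset shrinks differences of dim genes by construction) and 0 changed sign. Of 74 counts and sizes, 48 stayed within their limits, which were 1.5 times for counts and a narrower one for the ratios of effect sizes. The series matrix values moved none of these. Percentiles among random lists are not given for list medians under the alternatives. Neither normexp nor a change of scaling shifted the median of all genes by more than 0.031. Signal over background limits dim genes: 3946 of 27772 genes were above it on no array.

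Under normexp, the number of 2-fold genes was 183 for challenge in wild type, 692 in cells labelled Pla2g3-/- and 108 in both (95 higher and 13 lower), 451 and 429 for genotype without and with challenge and 99 in both, and 552 for the difference between challenge effects. The ratio of effect sizes was 2.13, and the additive fit called 9 genes for genotype. With only genes above background on all 4 arrays, which removes genes by construction, the counts were 453 for challenge in wild type and 961 for genotype under challenge, and the fit called 1 for genotype. With no filter on dim probes, which adds genes by construction, they were 1451 for challenge in wild type, 437 in both (253 higher and 184 lower), 1826 and 2398 for genotype without and with challenge (1225 higher and 1173 lower in the last) and 493 in both (266 and 227). With the control array labelled Pla2g3-/- in place of the wild-type one, challenge in wild type gave 1485 (526 and 959), and with the reverse exchange challenge in cells labelled Pla2g3-/- gave 951 and 753. With 1 control for both genotypes, which shares its chance values and may raise the overlap, challenge in both gave 393 with the wild-type control (219 and 174) and 693 with the other (228 and 465). By the limma additive fit the count in both was 4. Genes changed in either genotype gave a size ratio of 1.79. The fit for genotype called 5 genes under quantile normalization, 0 with the mean of a gene's probes and 0 without trend, and for challenge 0 without trend, where 2802 and 2813 genes had an unadjusted p under 0.05 for challenge and genotype.

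Under normexp, the medians that moved were: for challenge in wild type smooth muscle and pericytes −0.017, neutrophils 0.64, eosinophils −0.11, B and plasma cells −0.72, epithelial cytokines 0.22, tissue remodelling −0.01, secreted phospholipases A2 −0.017 and thymocytes (added) −0.27. For challenge in cells labelled Pla2g3-/- endothelial cells 0.11, cardiac muscle 0.087, neutrophils 1.09, dendritic cells 0.61, T cells −1.27, epithelial cytokines 0.85, immediate early 0.54, circadian clock −0.30, tissue remodelling 0.32 and thymocytes (added) −3.26. For genotype without challenge endothelial cells −0.24, smooth muscle and pericytes −0.054, neutrophils 0.38, T cells 2.25, B and plasma cells −0.80, immediate early −0.19, tissue remodelling −0.12, secreted phospholipases A2 0.036, thymocytes (added) 3.49 and thyroid and parathyroid (added) −0.11. For genotype under challenge tuft, ionocyte and neuroendocrine cells 0.45, fibroblasts 0.18, smooth muscle and pericytes −0.066, neutrophils 1.45, eosinophils 0.23, dendritic cells 0.49, T cells 0.68, natural killer cells 0.007, epithelial cytokines 0.71, chemokines 1.73, secreted phospholipases A2 −0.063, eicosanoid receptors 0.14 and thymocytes (added) 0.58. For the difference between challenge effects endothelial cells 0.16, smooth muscle and pericytes −0.062, mesothelial cells 0.48, dendritic cells 0.70, natural killer cells −0.076, B and plasma cells 0.88, type 2 epithelial response 0.10, epithelial cytokines 0.11, tissue remodelling 0.34, secreted phospholipases A2 −0.021, lysophospholipid genes −0.001 (0.13 otherwise), thymocytes (added) −2.78, T cell egress and memory (added) 0.61 and thyroid and parathyroid (added) 0.19.

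Under quantile normalization, the medians that moved were: for challenge in cells labelled Pla2g3-/- red cells and platelets −0.63, acute phase and antimicrobial 0.90, xenobiotic cytochromes P450 −0.26 and ribosomal proteins −0.14. For genotype without challenge mesothelial cells −0.25 and ribosomal proteins 0.002. For genotype under challenge club cells −0.05. For the difference between challenge effects club cells −0.045, goblet cells and mucus 0.023, alveolar type 1 cells 0.10, red cells and platelets −0.19, acute phase and antimicrobial 0.24, NRF2 and oxidative stress −0.021, hypoxia and glycolysis 0.079, oxidative phosphorylation −0.08 and ribosomal proteins −0.081.

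Under only genes above background on all 4 arrays, the medians that moved were: for challenge in wild type T cells −0.55 and epithelial cytokines 0.17. For challenge in cells labelled Pla2g3-/- endothelial cells 0.44, eosinophils 0.29, T cells −2.28, epithelial cytokines 0.63 and tissue remodelling 0.65. For genotype without challenge smooth muscle and pericytes −0.10 and tissue remodelling −0.16. For genotype under challenge smooth muscle and pericytes 0.25, red cells and platelets −0.10, epithelial cytokines 0.63, chemokines 1.76, eicosanoid receptors 0.59 and thyroid and parathyroid (added) 0.58.

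Under the mean of a gene's probes, the medians that moved were: for challenge in wild type dendritic cells −0.29, MHC class II presentation −0.39 and thymocytes (added) −0.51. For challenge in cells labelled Pla2g3-/- dendritic cells 0.52, cell cycle −0.54 and tissue remodelling 0.65. For genotype without challenge glucocorticoid response −0.31, secreted phospholipases A2 0.35 and thymocytes (added) 3.87. For genotype under challenge basal cells −0.14 and chemokines 1.76. For the difference between challenge effects endothelial cells 0.70, epithelial cytokines 0.68, secreted phospholipases A2 −0.043 and thymocytes (added) −3.03.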

Other observations

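No hypothesis is tested in this part, and the 2 lists marked as added and the 10 gene families were tests chosen only after the results were seen. Medians without a percentile lie outside the central 95% of random lists, as above.

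Several programmes differed by genotype in opposite directions without and with challenge. Tissue remodelling genes had a median of −0.41 between the control arrays (5 of 21 lower) and 0.36 between the challenged arrays (4 higher and 1 lower), and 8 of 21 were higher after challenge in cells labelled Pla2g3-/- (0.80). Under normexp the first and the last of these medians were −0.12 and 0.32, and with only genes above background on all 4 arrays the first was −0.16. Genes of antigen presentation on MHC class II had medians of −0.43 and 0.18, with challenge effects of −0.28 and 0.29, though none of 8 was at 2-fold in any. Heat shock genes were lower by genotype in both conditions (−0.42 and −0.21). Cholesterol synthesis genes had medians of 0.14 and −0.25, and none of 18 was at 2-fold. Complement genes had medians of 0.02 (54.9th percentile) and 0.50, with 4 of 16 higher after challenge in cells labelled Pla2g3-/-. Genes of the glucocorticoid response had challenge medians of −0.25 and −0.21, the second at the 3.24th percentile. The list of rare epithelial types (tuft cells, ionocytes and neuroendocrine cells) had genotype medians of 0.25 and 0.64.

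The remaining lists are given by their challenge medians in wild type and in cells labelled Pla2g3-/-. Alveolar type 2 genes had 0.13 and 0.14, and alveolar type 1 genes −0.25 and −0.08 (44.2nd percentile). Mesothelial genes had 0.04 (77.9th) and 0.46, smooth muscle genes −0.17 and −0.10 (20.1st and 41.3rd), and cardiac muscle genes 0.16 (97.0th) and 0.21 (0.087 under normexp). Mast cell and basophil genes had 0.19 and 0.03 (79.9th), and natural killer cell genes −0.11 and −0.14 (30.9th and 28.2nd). Genes of red cells and platelets had −0.40 and −0.74, with 1 of 11 lower in the first and 5 lower and 1 higher in the second. Hypoxia and glycolysis genes had 0.14 and 0.07 (95.8th), tight junction genes 0.07 (88.7th) and 0.12, and fatty acid genes −0.02 and −0.04 (43.5th and 54.5th). Genes of oxidative phosphorylation had 0.07 and −0.13 (90.7th and 37.8th), and ribosomal protein genes −0.03 (14.1th) and −0.27 (−0.14 under quantile normalization). The 2 sex-linked genes measured had medians of −0.41 and −0.45, with no percentile for so short a list. The added list of T cell egress and memory had −0.29 and 0.28, and the added thyroid and parathyroid list −0.07 and −0.22 (43.8th and 12.5th).

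Detection was counted in 10 gene families, many of them mostly used in other tissues. Of 1097 olfactory receptor genes, 433 and 425 were above background on the wild-type control array and that labelled Pla2g3-/-, 452 on the challenged wild-type array and 396 on the challenged array labelled Pla2g3-/-. Of 260 vomeronasal receptor genes 44.2%, 42.7%, 46.5% and 38.9% were, in the same order of arrays. In that order again, the counts were 31, 29, 34 and 30 of 53 for keratin-associated proteins, 19, 18, 19 and 18 of 43 for beta-defensins, and 16, 16, 16 and 14 of 18 for whey acidic protein domain genes. Mbd3l genes gave 0, 0, 2 and 1 of 2, and histones 15, 16, 16 and 15 of 16. Bitter taste receptors (8, 9, 8 and 10 of 35) and Mrgpr receptors (13, 13, 14 and 15 of 23) were instead most often above background on the challenged array labelled Pla2g3-/-, and Serpina3 genes did not differ (10 of 11 on each).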
